A study of Mus musculus with 9 samples.

How the data were processed

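Brain RNA of adult male C57BL/6 mice was hybridised to 9 1-colour Agilent arrays, 3 per group. Per the labels, sham mice had sham surgery, with no injection stated for them, and the part of the brain used is not stated. MCAO mice had the middle cerebral artery closed for 90 min and received 1 µl of phosphate-buffered saline in the right lateral ventricle 3 h after reperfusion. VEGF mice had the same occlusion and received 1 µl of recombinant human VEGF-A165 at 10 µg/ml by the same route. All brains were taken 24 h after reperfusion, which is 21 h after the injection, at an age of 50 to 53 days. Per the labels, 200 ng of RNA was labelled with Cy3 for each array, and different mice were used for the 3 experiments, so the arrays of a group are separate animals.

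The deposited scanner files hold intensity values for 62976 spots per array, of which 3671 are controls. Per the file headers, Feature Extraction 10.7.1.1 subtracted the background, divided by a spatial trend and replaced values near background by a surrogate to give the processed intensity, which is not scaled between arrays. The detrending factor is deposited per spot as a ratio around 1, and per the file headers MCAO array 1 was processed without it. The authors also deposited a table of values whose scale is not stated. Its columns correlate at 0.998 to 1.00 with the log2 processed intensity of the matching array and each has a median of 6.97, so it is read as log2 values made alike between arrays. The method of that step is not stated. Tested below, the table called 1012 genes in MCAO against sham and 924 in VEGF against sham, where quantile normalization called 1011 and 923. These 2 alternatives are therefore close to the same check. All 3 sham arrays lie on 1 slide and all 6 ischaemic arrays on another. MCAO array 1 was scanned on another day than the other 8 arrays.

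From these files, log2 of the processed intensity minus each array's 75th percentile over non-control probes was computed, with spots of a probe averaged. Of 55681 non-control probes, 43921 were well above background on all 3 arrays of at least 1 group and were kept. A gene symbol came from the array's RefSeq accession through a RefSeq table of the GRCm38.p6 assembly, matched without versions, for 26582 of the non-control probes; other probes keep the array's own name. No coordinates are given. The brightest probe stood for a gene with several (7936 of the 30837 tested items), and items comprise 17589 with a symbol and 13248 without. Items of both kinds are called genes below. Outlier spots were left out unless all spots of a probe were marked so, and no spot was saturated.

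Groups were compared with limma 3.58.1 in R 4.3.3 (statmod 1.5.0) in a single fit of all 9 arrays without covariates, with moderated two-sided tests and Benjamini-Hochberg adjustment at 0.05. The fit gave 8.48 degrees of freedom, of which 2.48 came from the prior, a median standard error of 0.31 and a median 95% half-width of 0.71 log2 units. The number of arrays limits the precision. Values after ± are standard errors of the fit with n = 3 arrays per group. Where no array of the dimmer group was well above background, the difference is given as at least N-fold: the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. On data simulated with independent noise over 30837 genes (200 changed genes in each of 5 draws), the fit recovered 11.2% of 2-fold, 62.4% of 4-fold, 82.4% of 8-fold and 86.8% of 16-fold changes between VEGF and MCAO. For MCAO against sham it recovered 9.2%, 55.6%, 80.4% and 90.8%, and for VEGF against sham 15.6%, 54%, 73.6% and 89.6%.

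There were 41 gene lists with 605 genes in all, 587 of them measured, on pathways, cell types and brain regions. They were tested with limma's camera at its preset correlation of 0.01 between genes, adjusted over the 41 lists, and again with a correlation estimated from the arrays. In data simulated with independent noise and randomly drawn lists, camera found 25 of 25 lists of 15 genes shifted by 1 log2 unit and no other list. Genes in that simulation are uncorrelated, so it cannot show how often lists pass through correlation between their genes. The correlation estimated from the arrays was 0.89 for neuron markers. limma's fry, which asks whether a list's genes move one way and compares them with no other genes, was run beside it. An ischaemia signature was scored per array as the mean of the genes higher minus the mean of the genes lower in all 6 ischaemic arrays against sham. It was compared between VEGF and MCAO by an exact two-sided permutation test, whose smallest p with 3 against 3 is 0.1. Under each alternative its genes were chosen anew.

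The groups, tests, lists, alternatives and naming rule were set before the data were examined. Genes are named by that rule: the 10 largest rises and 10 largest falls that passed, with groups that do not overlap and a probe well above background in the higher group, passing over accession-like and predicted names. Where fewer than 10 passed, genes of smallest unadjusted p up to 5 per direction, are given as values that did not pass. Also named are up to 4 members of each list past the threshold and of 4 lists of direct interest (VEGF and endothelial response, endothelial markers, cytokines, growth factors), always Vegfa, Flt1, Kdr and Nrp1, and genes called in MCAO against sham and in the opposite direction in VEGF against MCAO. The alternatives cover normalization, background correction, filters, probe choice, covariates, array weights, the authors' value table and leaving out each array.

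The processed intensity of each spot was also recomputed as its background-subtracted signal divided by its detrending factor (no division on MCAO array 1, surrogates kept). The deposited value departed from the recomputed one by more than 0.1 log2 units in 14 non-control probes, on 8 to 12 spots per array, and in 0 control spots. Of the 14 probes, 7 departed on all 9 arrays, and the rest departed by group. Orm3, Nhs, Plxnc1 and a probe without a symbol departed on the 3 MCAO arrays only. A C3 probe departed on the sham and VEGF arrays only, and Orm1 on the sham and MCAO arrays only. Another probe without a symbol departed on VEGF arrays 1 and 2 only. The main values use the deposited signals, and recomputed ones are printed beside them. This recomputation, leaving out the 14 probes, leaving out MCAO array 1 and VEGF array 1 together, a replicate block within the 6 ischaemic arrays, a test of named genes only and the naming rule applied without the 14 probes were all chosen after the data were seen.

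Replicate numbers in the labels were checked for pairing through deviations from the group means. Between MCAO and VEGF, same-numbered arrays correlated at 0.59, 0.22 and 0.56 across genes, all above 0.1. MCAO array 2 correlated better with VEGF array 3 (0.39), and MCAO array 3 with VEGF array 2 stood at 0.23. Deviations within a group cancel out, so with arrays 1 apart in both groups, arrays 2 and 3 tend to correlate under either matching. The check therefore cannot establish pairing, which the labels do not state, and the numbers were used as a possible pairing only. Sham arrays were not paired with the others, with 0.03, -0.11 and 0.15 against MCAO and -0.03, 0.14 and 0.11 against VEGF.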

Results

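The series measured gene expression in the brain of mice 24 h after reperfusion in 3 groups of 3: sham surgery, middle cerebral artery occlusion with vehicle (MCAO), and occlusion with VEGF-A, a growth factor of blood vessels, injected into the ventricle (VEGF). Per the title, it asks how VEGF affects the expression profile after focal ischaemia. Between 73.0% and 81.8% of non-control spots were well above background. The 75th percentile signal was 1420, 1530 and 1530 on the sham arrays, 923, 2070 and 1980 on the MCAO arrays and 848, 1830 and 1540 on the VEGF arrays. Array pairs within sham correlated at 0.99 to 0.993, within MCAO at 0.949 to 0.993, within VEGF at 0.951 to 0.983, and sham with ischaemic arrays at 0.910 to 0.974. These are correlations across probes, which are not independent replicates.

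The first principal component held 57.0% of the variance and separated sham, with scores from -104 to -90.1, from the ischaemic arrays. MCAO array 1 and VEGF array 1 scored 130 and 141, and the other 4 ischaemic arrays lay between -8.17 and 15.9. On these 2 arrays the median of 16 neuron markers was -2.43 log2 units relative to sham on both, against -0.63 to -0.30 on the other ischaemic arrays. The median of 18 endothelial markers was 1.90 on MCAO array 1 and 2.52 on VEGF array 1, against 0.21 to 0.65 on the others. Leading counts are therefore also given without this pair of arrays. The slide cannot be told apart from ischaemia, since sham and ischaemic arrays were on different slides. Nor can the ventricular injection, which the labels state for MCAO and VEGF mice only. MCAO and VEGF shared a slide.

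**Figure D1:**
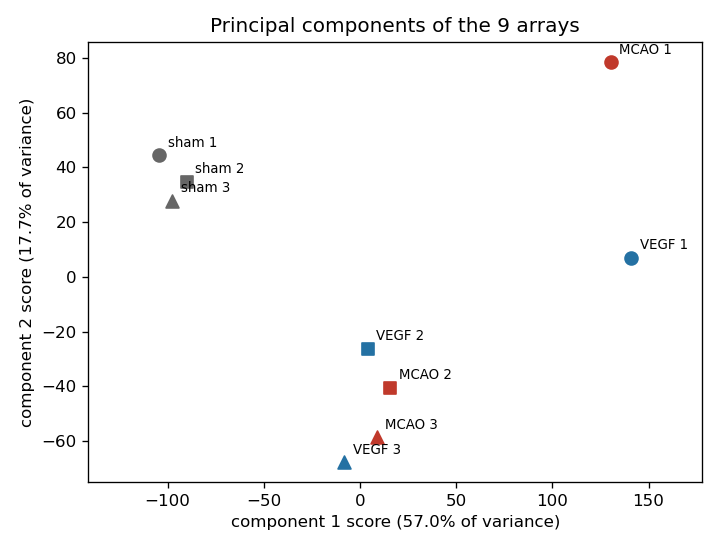
Scores of the 9 arrays on the first (57.0% of variance) and second (17.7%) principal components of the genes tested, coloured by group. The sham arrays lie at -104 to -90.1 on the first, 4 ischaemic arrays at -8.17 to 15.9, and MCAO 1 and VEGF 1 at 130 and 141.

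The first comparison asked what ischaemia with vehicle changed. In MCAO against sham the matrix protease Mmp3 rose at least 576-fold, the macrophage scavenger receptor Msr1 at least 168-fold, the C-type lectin Clec4e at least 133-fold and Slfn4 at least 75.2-fold, all 4 not well above background on any sham array. The monocyte attractant Ccl2 rose by 8.49 ± 0.63 log2 units (limma adjusted p = 0.00061) and the chemokine Ccl4 by 7.73 ± 0.50. Genes that fell included Fibcd1 (-4.49 ± 0.84), the fructose transporter gene Slc2a5 (-3.30 ± 0.46) and Ankrd63 (-3.65 ± 0.49). In all, limma called 868 of 30837 genes, 703 higher and 165 lower, and 6593 had unadjusted p under 0.05.

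Other large rises were the acute-phase gene Saa3 (10.43 ± 1.02, well above background on 1 of 3 sham arrays), the cytokine Il6 (8.59 ± 1.30, 2 of 3), Clec4d (8.47 ± 0.75, 1 of 3) and the chemokine Cxcl1 (7.68, limma adjusted p = 0.0107). Retnla fell at least 6.65-fold and Igbp1b at least 4.94-fold, neither well above background on any MCAO array. Further falls were Plcz1 (-3.86 ± 0.76), the nicotinic receptor subunit gene Chrna10 (-3.18 ± 0.58), Myoc (-2.95 ± 0.38) and Upk1b (-2.84 ± 0.47), and Trdn fell at least 3.01-fold. Ccl4, Cxcl1 and Trdn came in when the naming rule was applied without the probes of discrepant signal, chosen after their values were seen. The acute-phase genes Orm1 and Orm2 also passed with the deposited signals (13.93 ± 0.42 and 8.27 ± 0.61), where recomputed signals gave 1.99 (limma adjusted p = 0.0813) and 2.33 (0.00614). Prr7 fell by 3.11 with deposited and by 2.55 with recomputed signals (limma adjusted p = 0.0430).

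Groups that did not overlap were found for 40.3% of genes, against 10% by chance. The count of called genes was 190 without sham array 1, 256 without sham array 2, 248 without sham array 3, 525 without MCAO array 2, 383 without MCAO array 3 and 2583 without VEGF array 1. Without MCAO array 1 it was 1177, of which 50.3% were higher, against 81.0% in the fit of all arrays. Without both MCAO array 1 and VEGF array 1 it was 7028, of which 42.9% were higher. Fitting only the 2 groups gave 1788 genes, age as a covariate 1594 and normexp background correction 556.

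Inflammatory gene lists rose as groups. Of 23 measured cytokines and chemokines, 18 rose (22 adjusted over the list alone, and 21 over all genes without the pair of arrays). Those of smallest p were Ccl3 (7.60 ± 0.47), Ccl4, Ccl12 (5.44 ± 0.38) and Ccl2. The list passed limma's camera with adjusted p = 4.06e-25 (adjusted p = 0.128 with an estimated correlation). Of 18 genes of activated microglia and macrophages, 14 rose (16 adjusted over the list alone), among them the oxysterol enzyme Ch25h (5.33 ± 0.30), Ms4a6d (5.32 ± 0.36) and the pattern receptor Tlr2 (4.19 ± 0.37). Activated microglia genes passed as a list with adjusted p = 3.11e-23 (adjusted p = 0.128 with an estimated correlation). Of 21 reactive astrocyte genes, 17 rose (21 adjusted over the list alone), with the siderophore-binding Lcn2 at 6.82 ± 0.34, the oncostatin M receptor gene Osmr at 3.68 ± 0.21 and Serpina3n at 4.63 ± 0.38. Reactive astrocyte genes passed as a list with adjusted p = 6.92e-27 (adjusted p = 0.0807 with an estimated correlation). Of 15 neutrophil genes, 7 rose (10 adjusted over the list alone), including the chemokine receptor Cxcr2 (at least 24.5-fold), Il1r2 (4.41 ± 0.65) and S100a9 (6.04 ± 0.92). Neutrophil genes passed as a list with adjusted p = 4.26e-08 (adjusted p = 0.307 with an estimated correlation). Of 14 complement genes, 7 rose (12 adjusted over the list alone), such as the anaphylatoxin receptor gene C5ar1 (6.51 ± 0.51), C3 (2.77 ± 0.25, on a probe whose signals matched) and Cfb (5.29 ± 0.57). Another C3 probe, of discrepant signal, stood at 5.97 with deposited and 5.26 with recomputed signals. Complement genes passed as a list with adjusted p = 2.64e-10 (adjusted p = 0.128 with an estimated correlation). Of 19 interferon-stimulated genes, 14 rose (18 adjusted over the list alone), such as Gbp2 (2.63 ± 0.23), Cxcl10 (5.16 ± 0.70), Bst2 (3.15 ± 0.44) and Ifitm3 (3.42 ± 0.52). Interferon-stimulated genes passed as a list with adjusted p = 1.01e-16 (adjusted p = 0.190 with an estimated correlation). On MCAO array 1 and VEGF array 1 the medians were 6.09 and 5.92 for cytokines (3.90 to 5.85 on the other ischaemic arrays), 5 and 5.41 for activated microglia (3.76 to 4.59), 4.11 and 4.08 for reactive astrocyte (2.96 to 3.49) and 5.22 and 4.71 for neutrophil genes (1.52 to 4.38).

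Genes of leukocyte adhesion and lymphocytes passed with fewer members called. Of 10 adhesion genes 3 rose, among them the selectin gene Sele (at least 6.36-fold) and the integrin ligand gene Icam1 (3.19 ± 0.47), with 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00392, adjusted p = 0.371 with an estimated correlation). Of 12 lymphocyte genes 2 rose, also 2 adjusted over the list alone, the T cell gene Cd3d (2.26 ± 0.29) and granzyme gene Gzmb (2.11 ± 0.33), adjusted p = 0.0456, adjusted p = 0.507 with an estimated correlation, and adjusted p = 0.351 without the pair of arrays (median 0.13). The medians on MCAO array 1 and VEGF array 1 were 2.24 and 2.23 for adhesion genes, against 0.86 to 1.07 on the other ischaemic arrays, and 1.04 and 0.81 for lymphocyte genes, against 0.04 to 0.32. Among 12 homeostatic microglia markers the purinergic receptor gene P2ry12 fell by 2.67 and 11 did not pass; adjusted over the list alone 1 was higher and 4 lower. The list did not pass (adjusted p = 0.470), and its median (0.30) and mean (-0.20) differed in sign.

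Stress and injury lists also rose. Of 21 p53 targets and apoptosis genes, 7 rose (17 adjusted over the list alone), with the Fn14 receptor gene Tnfrsf12a at 5.12 ± 0.55, the BH3-only gene Pmaip1 at 3.23 ± 0.36, Tnfrsf1a at 2.87 ± 0.36 and Fas at 2.54 ± 0.34; camera adjusted p = 2.14e-13, and adjusted p = 0.194 with an estimated correlation. Of 15 oxidative stress and metal response genes, 5 rose (9 adjusted over the list alone), including thioredoxin reductase Txnrd1 (1.79 ± 0.28), metallothionein Mt2 (1.70 ± 0.28) and haem oxygenase Hmox1 (4.88 ± 0.86). Oxidative stress genes passed as a list with adjusted p = 2.54e-06 (adjusted p = 0.292 with an estimated correlation). Of 15 unfolded protein and integrated stress response genes, 3 rose (9 adjusted over the list alone): Sdf2l1 (1.26 ± 0.24), Trib3 (4.33 ± 0.87) and Chac1. Stress response genes passed as a list with adjusted p = 1.58e-05 (adjusted p = 0.216 with an estimated correlation). Of 14 heat shock and chaperone genes, the small heat shock genes Hspb1 (4.52 ± 0.41) and Hspb8 (1.48 ± 0.32) rose (6 adjusted over the list alone), and Hspa1a stood at 4.44 ± 1.06 without passing. Heat shock genes passed as a list with adjusted p = 0.000100 (adjusted p = 0.382 with an estimated correlation). Of 14 glucocorticoid response genes, 4 rose (7 adjusted over the list alone), the cell cycle inhibitor Cdkn1a (3.87 ± 0.65), Fkbp5 (1.39 ± 0.24), Sgk1 (1.84 ± 0.34) and Plin4 (4.22 ± 0.84). Glucocorticoid response genes passed as a list with adjusted p = 3.05e-05 (adjusted p = 0.148 with an estimated correlation). Of 19 immediate early genes, Atf3 (6.98 ± 0.73), Fosl1 (4.71 ± 0.82) and Ier3 (3.23 ± 0.64) rose and Egr4 fell (-2.65 ± 0.35), the same counts as adjusted over the list alone. That list's adjusted p = 0.0396 became adjusted p = 0.713 with an estimated correlation and adjusted p = 0.0714 (median 0.42) without the pair of arrays, on which its medians were 1.72 and 2.24, against -0.25 to 0.43 on the other ischaemic arrays. The pair also stood apart in heat shock genes (1.16 and 1.23, against 0.40 to 0.71), p53 targets (2.76 and 2.38, 1.15 to 1.55) and oxidative stress genes (1.29 and 1.77, 0.64 to 1.02). The same held for unfolded protein response (1.09 and 1.35, 0.69 to 0.73) and glucocorticoid response genes (1.53 and 1.33, 0.78 to 1.01).

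Vascular, hypoxia and matrix genes moved in part. Of 23 protease and extracellular matrix genes, 10 rose (20 adjusted over the list alone), with the inhibitor Timp1 at 6.70 ± 0.46, osteopontin (Spp1) at 5.29 ± 0.65 and the urokinase receptor gene Plaur at 5.51 ± 0.77. Its adjusted p = 1.15e-15, and adjusted p = 0.292 with an estimated correlation; its medians were 3.76 and 4.36 on MCAO array 1 and VEGF array 1, against 1.91 to 2.48 on the other ischaemic arrays. Of 18 hypoxia response genes, 4 rose (6 adjusted over the list alone), among them Adm (2.67 ± 0.29), hexokinase Hk2 (2.34 ± 0.33) and Plin2 (3.94 ± 0.80). Hypoxia response genes passed as a list with adjusted p = 0.00618 (adjusted p = 0.292 with an estimated correlation). Among 25 VEGF ligands, receptors and endothelial response genes, the protease Adamts1 (4.25 ± 0.67) and the Tie2 ligand gene Angpt2 (3.56 ± 0.61) rose, also 2 adjusted over the list alone. VEGF response genes passed as a list with adjusted p = 0.0169 (adjusted p = 0.539 with an estimated correlation), with medians of 0.80 and 1.16 on MCAO array 1 and VEGF array 1, against 0.12 to 0.43 on the other ischaemic arrays. Vegfa stood at 0.21 ± 0.38 (limma adjusted p = 0.776), its receptor genes Flt1 at 1.18 ± 0.61 (0.293) and Kdr at -0.05 ± 0.18 (0.890), and the co-receptor gene Nrp1 at -0.24 ± 0.28 (0.635), none of them called. The 2 probes of Kdr had opposite signs, and Nrp1 stood at 0.38 with array weights. Of 18 endothelial markers, Itm2a fell (-1.96 ± 0.36), and 6 were higher and 2 lower adjusted over the list alone. Endothelial markers passed as a list with adjusted p = 0.0108 (adjusted p = 0.642 with an estimated correlation). The medians of this list on MCAO array 1 and VEGF array 1, given above, exceeded those of the other ischaemic arrays. Of 11 pericyte and smooth muscle markers none was called by limma (2 lower adjusted over the list alone; 7 at unadjusted p under 0.05), and median (0.21) and test (down, adjusted p = 0.702) differed in sign.

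Neuronal lists were lower as groups with few members called. Of 16 neuron markers 0 were called by limma, and 0 adjusted over the list alone, with all 16 below 0. At limma's unadjusted p under 0.05 were 4 of 16, against 6593 of all 30837 genes. The tubulin gene Tubb3 stood at -1.39 ± 0.43 and the synaptic vesicle gene Syp at -1.51 ± 0.60. The list's median was -1.15 (camera adjusted p = 0.000375, adjusted p = 0.507 with an estimated correlation), and -0.49 without the pair of arrays, with 5 members lower. Of 18 glutamate and GABA receptor genes Gabra2 fell (-2.05 ± 0.39), also 1 adjusted over the list alone; the median was -1.30 (adjusted p = 3.87e-05, adjusted p = 0.507 with an estimated correlation), and -0.70 without the pair of arrays, with 10 members lower. Its medians were -2.92 and -2.90 on MCAO array 1 and VEGF array 1, against -0.78 to -0.51 on the other ischaemic arrays. Striatal medium spiny neuron markers had a median of -1.36 (5 of 14 lower adjusted over the list alone, adjusted p = 5.09e-05, adjusted p = 0.399 with an estimated correlation), with Gng7 at -1.31 ± 0.34 and Pde10a at -2.05 ± 0.56, neither called over all genes. Interneuron and neuropeptide genes had a median of -0.86 (0 of 13 adjusted over the list alone, adjusted p = 0.00392, adjusted p = 0.132 with an estimated correlation, adjusted p = 0.0714 and median -0.61 without the pair of arrays). Of 12 cortex and hippocampus markers Rasgrf2 fell (-0.81 ± 0.16), also 1 adjusted over the list alone, adjusted p = 0.0216, adjusted p = 0.507 with an estimated correlation, and adjusted p = 0.351 without the pair of arrays (median -0.31). This list had medians of -2.06 and -2.33 on MCAO array 1 and VEGF array 1, against -1.47 to 0.01 on the other ischaemic arrays. For striatal markers they were -2.22 and -2.01, against -1.32 to -0.70, and for interneuron genes -1.68 and -0.91, against -0.80 to -0.23.

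Other lists past the threshold had 0 to 2 called members. The growth factor genes Fgf2 (2.60 ± 0.41) and Hbegf (2.65 ± 0.50) rose among 18 neurotrophic and growth factors, with 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0396, adjusted p = 0.497 with an estimated correlation). In 4 lists limma called 0 members, with 5 of 6, 3 of 14, 4 of 15 and 1 of 17 at unadjusted p under 0.05 in the order that follows. Over all genes this held for 6593 of 30837. Red blood cell genes had a median of 1.14 (5 of 6 higher adjusted over the list alone, adjusted p = 0.00190, adjusted p = 0.389 with an estimated correlation). Oligodendrocyte and myelin genes had a median of 0.99 (0 of 14 adjusted over the list alone, adjusted p = 0.0108, adjusted p = 0.539 with an estimated correlation, adjusted p = 0.115 and median 0.51 without the pair of arrays), with Mobp at 1.92 ± 0.59, and Mbp at 1.18 ± 0.58, with 2 of its other probes of opposite sign. Cell division genes had a median of 0.45 (0 of 15, adjusted p = 0.0239, adjusted p = 0.507 with an estimated correlation, adjusted p = 0.0501 and median 0.28 without the pair). Oxidative phosphorylation genes had a median of -0.24 (0 of 17, adjusted p = 0.0155, adjusted p = 0.539 with an estimated correlation, adjusted p = 0.0714 and median -0.20 without the pair). On MCAO array 1 and VEGF array 1 growth factors had medians of 0.61 and 1.1 (0.08 to 0.31 on the other ischaemic arrays), red blood cell genes 1.40 and 1.65 (0.68 to 0.99) and oxidative phosphorylation genes -0.33 and -0.34 (-0.23 to 0.08).

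The remaining lists did not pass in MCAO against sham. Adjusted p was 0.360 for astrocyte markers (median -0.17), 0.213 for neurogenesis and progenitor genes (-0.40), 0.162 for water channels and ion pumps (-0.35), 0.666 for cholesterol synthesis (-0.01), 0.905 for choroid plexus markers (0.27) and 0.913 for ependymal and cilia genes (0.17). It was 0.666 for meningeal and fibroblast genes (-0.14), 0.266 for cerebellum markers (-0.25), 0.666 for thalamus and midbrain markers (-0.27), 0.322 for pituitary and hypothalamus markers (-1.05) and 0.666 for reference genes (-0.02). Median, mean and test differed in sign for cholesterol synthesis, ependymal and cilia genes and reference genes. In all, 28 lists passed, 22 higher and 6 lower, and none of the 28 held with an estimated correlation. Without the pair of arrays 21 passed. Of these, reactive astrocyte (adjusted p = 0.0362), activated microglia and macrophage (0.0228), protease (0.0228) and complement genes (0.0434) also held with an estimated correlation. Reactive astrocyte genes also held with median centring (0.0245), normexp (0.0478) and without VEGF array 1 (0.0172), and complement genes with median centring (0.0269) and without VEGF array 1 (0.0203). fry, which compares a list with no other genes, passed 15.

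Of the 28 lists, 18 passed camera with each array left out in turn. The other 10 lost their call as follows, with median and adjusted p in brackets, without MCAO array 1: immediate early genes (0.42, 0.157), lymphocyte genes (0.13, 0.424), neuron markers (-0.49, 0.157), myelin genes (0.51, 0.0875), oxidative phosphorylation (-0.20, 0.138) and cortex and hippocampus markers (-0.31, 0.429). Without MCAO array 2 these were immediate early genes (0.76, 0.0710), hypoxia response (0.18, 0.0651), VEGF response (0.49, 0.0815), cell division (0.34, 0.159) and growth factors (0.37, 0.0914). Without sham array 1 these were immediate early genes (0.59, 0.102), cell division (0.29, 0.0663) and myelin genes (0.73, 0.102). Without sham array 2 these were immediate early genes (0.46, 0.109) and lymphocyte genes (0.47, 0.0757). Without sham array 3 these were lymphocyte genes (0.36, 0.0783), growth factors (0.31, 0.0659) and cortex and hippocampus markers (-0.76, 0.0636). Lymphocyte genes also missed the threshold with quantile normalization (0.33, 0.0571), median centring (0.37, 0.0604), normexp (0.19, 0.139), the filter on all 9 arrays (0.36, 0.0620), the authors' value table (0.33, 0.0573) and named genes only (0.44, 0.0629). Growth factors missed it with normexp (0.38, 0.0522), the filter on all 9 arrays (0.35, 0.0584), the mean of a gene's probes (0.50, 0.0573), the replicate number as a block in all 9 arrays (0.36, 0.0572) and named genes only (0.36, 0.0546). Immediate early genes missed it with named genes only (0.60, 0.0546). With array weights lymphocyte genes (0.36, 0.175) and cortex and hippocampus markers (-0.44, 0.354) missed it, and with a variance trend lymphocyte genes (0.44, 0.0562).

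**Figure D2:**
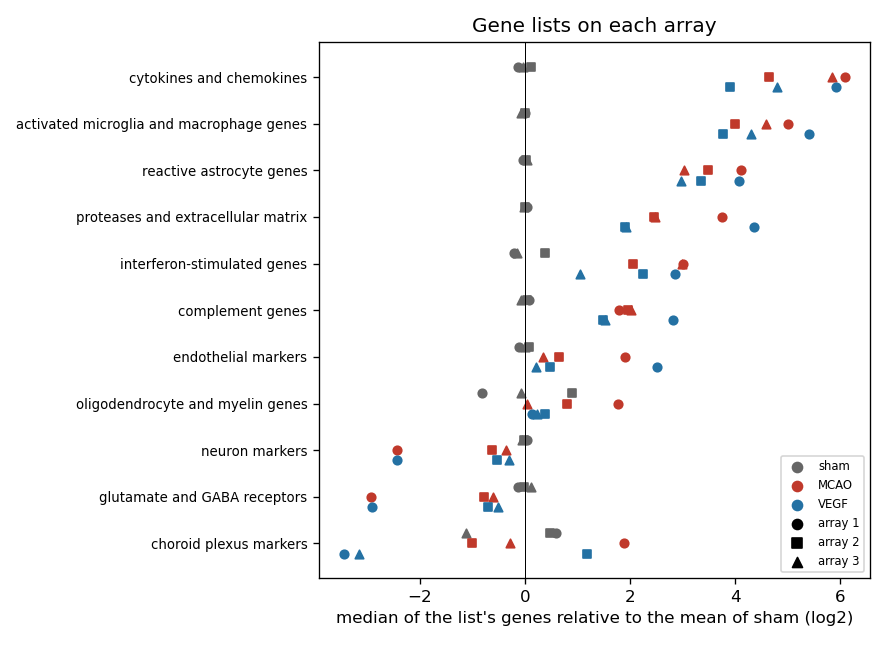
Median of each of 11 gene lists on each array, in log2 units relative to the mean of sham, coloured by group with a marker shape per array number. Neuron markers stand at -2.43 on MCAO 1 and on VEGF 1 and at -0.63 to -0.30 on the other ischaemic arrays, and choroid plexus markers run from -3.43 on VEGF 1 to 1.89 on MCAO 1.

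The next comparison asked what VEGF changed in the ischaemic brain. With the deposited signals, 2 of 30837 genes were called in VEGF against MCAO, both acute-phase genes that had risen in MCAO against sham: Orm1 fell by 12.56 ± 0.42 log2 units (limma adjusted p = 2.19e-05) and Orm2 fell by 7.56 ± 0.61 (0.0146). With the signals recomputed from the same spots neither was called: Orm1 stood at -2.35 ± 0.51 (limma adjusted p = 1.00) and Orm2 at -2.40 ± 0.29 (0.712). On MCAO array 2, the Orm1 spot had a mean pixel brightness of 64.2 and a deposited processed signal of 73900. Genes of the VEGF pathway did not pass: Vegfa stood at -0.26 ± 0.38, Flt1 at 0.04 ± 0.61, Kdr at 0.26 ± 0.18 (its 2 probes of opposite sign) and Nrp1 at 0.17 ± 0.28 (-0.45 with array weights), each with adjusted p = 1.00.

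For the 14 probes with discrepant signals, VEGF minus MCAO and MCAO minus sham had opposite signs in all 14, with deposited and with recomputed signals alike. So had 55.7% of all genes; the 2 differences share the MCAO arrays. The deposited VEGF minus MCAO difference was larger than the recomputed one in 13 of 14, with Otud7b the exception, and had the same sign in 14. Orm3, another gene of the family, stood at -5.56 ± 0.56 with deposited signals (limma adjusted p = 0.0595) and at -2.20 with recomputed ones. Prr7 stood at 3.00 with deposited and 2.02 with recomputed signals, and Iho1 at 2.54 and 0.93. Nhs stood at 2.54 log2 units with deposited signals (at least 2.15-fold as a lower bound) and at 1.07 log2 units with recomputed ones. None of Prr7, Iho1 and Nhs passed. Recomputed signals for all probes gave 0 called genes in limma, with 865 at unadjusted p under 0.05, against 856 with the deposited ones. Leaving out the 14 probes gave 0 and 846.

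**Figure D3:**
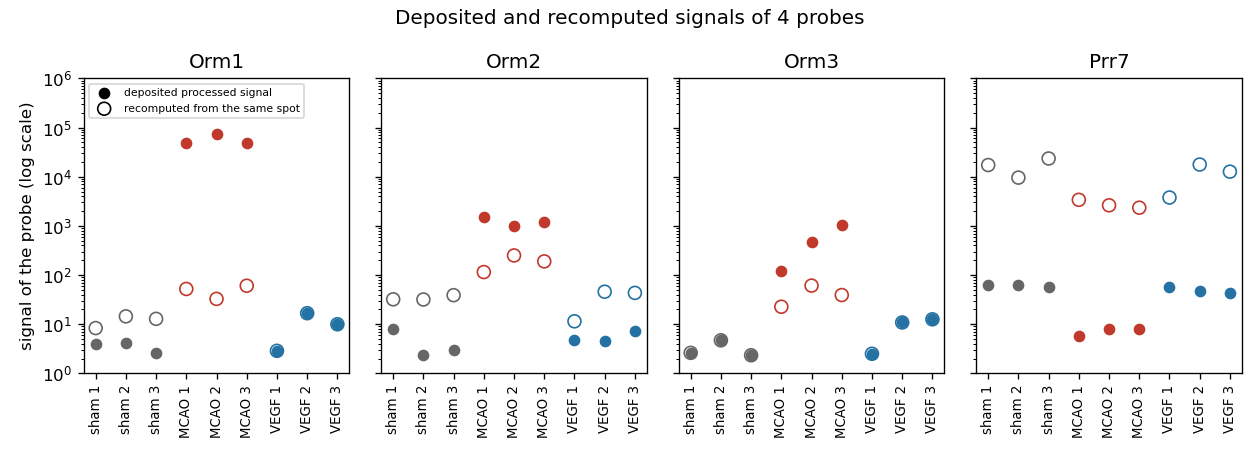
Signals of the Orm1, Orm2, Orm3 and Prr7 probes on each array on a log axis, filled for the deposited processed signal and open for the value recomputed from the same spot. For Orm1, deposited values on the MCAO arrays are 48800, 73900 and 48400 where recomputed ones are 52.1, 32.7 and 60.6.

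Among genes with matching signals, those of small unadjusted p included differences that did not pass: nonagouti at 1.79 ± 0.42, Olfr1000 at -1.84 ± 0.32 and Spopfm2 at -1.61 ± 0.29. The naming rule applied without the 14 probes, chosen after their values were seen, added Myom2 (1.21 ± 0.30), Igf2os (0.88 ± 0.24), Zic2 (1.13 ± 0.31), Pot1b (-0.86 ± 0.17), Pou5f2 (-1.05 ± 0.21) and Tecta (-1.06 ± 0.23), each with limma adjusted p = 1.00. Groups that did not overlap were found for 5.80% of genes, against 10% by chance for exchangeable arrays, which takes no account of any pairing of MCAO and VEGF arrays. With the replicate number as a block in the 6 ischaemic arrays, 0 genes were called in limma and 1164 had unadjusted p under 0.05. With deposited signals the count was 1 without sham array 3, MCAO array 2, MCAO array 3 or any of the 3 VEGF arrays in turn, and 3 without MCAO array 1. Without both MCAO array 1 and VEGF array 1 it was 3, and 0 with recomputed signals (2270 at unadjusted p under 0.05). normexp gave 0 genes (280 at unadjusted p under 0.05), quantile normalization 4, fitting only the 2 groups 1, and a filter on all 9 arrays 0 (580).

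Between VEGF and MCAO, 12 of 41 lists passed camera with its preset correlation, 9 higher and 3 lower; none held with an estimated correlation, none passed with each array left out in turn, fry passed 0, and limma called 0 members of any of them (856 genes had unadjusted p under 0.05 over all genes). Interferon-stimulated genes were lower as a list, with a median of -0.57 and 18 of 19 members below 0 (adjusted p = 0.00197, adjusted p = 0.764 with an estimated correlation); Bst2 stood at -1.05 ± 0.44 and Isg15 at -0.86 ± 0.53. Its medians were 3.02, 2.06 and 3.00 on the MCAO and 2.85, 2.24 and 1.05 on the VEGF arrays. Without VEGF array 3 the difference was -0.0713 (adjusted p = 0.524) and without MCAO array 3 it was -0.43 (0.292). Without the pair of arrays it was -0.61, with camera adjusted p = 0.000294 (adjusted p = 0.679 with an estimated correlation). Heat shock genes were higher by a median of 0.25 with 12 of 14 members above 0 (adjusted p = 0.00318, adjusted p = 0.764 with an estimated correlation), with Dnaja1 at 0.36 ± 0.16 and Hsp90aa1 at 0.30 ± 0.19, and 0.25 without the pair. Oxidative phosphorylation genes were higher by 0.16 in all 17 members (adjusted p = 0.000691, adjusted p = 0.764 with an estimated correlation), with Cs at 0.24 ± 0.17 and Cox4i1 at 0.24 ± 0.19, and 0.25 without the pair. Interneuron and neuropeptide genes were higher by 0.40 (adjusted p = 0.00197, adjusted p = 0.370 with an estimated correlation), with Calb2 at 1.40 ± 0.71 and Trh at 1.46 ± 1.04; without the pair the median was 0.40 and adjusted p = 0.0775.

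Of the 12 lists, 5 on cell types did not pass without both MCAO array 1 and VEGF array 1. Astrocyte markers were higher by a median of 0.27 (adjusted p = 0.000389, adjusted p = 0.764 with an estimated correlation), with the growth factor receptor gene Fgfr3 at 0.67 ± 0.20, and stood at -0.04 without the pair. The median on VEGF array 1 was 0.67, and -0.25 to -0.08 on the other ischaemic arrays. Homeostatic microglia markers were higher by 0.33 in all 12 members (adjusted p = 0.000261, adjusted p = 0.764 with an estimated correlation), with Tmem119 at 0.66 ± 0.25; the median on VEGF array 1 was 0.71, and without the pair the difference was 0.12 (adjusted p = 0.403). Pericyte and smooth muscle markers were higher by 0.24 (adjusted p = 0.00254, adjusted p = 0.764 with an estimated correlation), with Vtn at 0.86 ± 0.32, and stood at -0.13 without the pair. Meningeal and fibroblast genes were higher by 0.66 (adjusted p = 0.000261, adjusted p = 0.764 with an estimated correlation), with Ogn at 1.07 ± 0.48 and the collagen gene Col1a2 at 0.66 ± 0.38, and stood at -0.04 without the pair; their median was 1.28 on VEGF array 1. Oligodendrocyte and myelin genes had a median of -0.58, with all 14 members below 0 (adjusted p = 0.00704, adjusted p = 0.764 with an estimated correlation), with Mog at -0.70 ± 0.43 and Opalin at -1.20 ± 0.77, and stood at 0.01 without the pair; their median was 1.77 on MCAO array 1.

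Lists of nearby tissue passed as well. Choroid plexus markers had a median of -1.28, with all 12 members below 0 (adjusted p = 0.00197, adjusted p = 0.764 with an estimated correlation), with the thyroxine carrier gene Ttr at -5.15 ± 2.15 and the folate receptor gene Folr1 at -2.89 ± 1.62, and stood at 0.06 without the pair. Pituitary and hypothalamus markers were higher by 1.33 (adjusted p = 0.0285, adjusted p = 0.764 with an estimated correlation), with Ghrh at 0.87 ± 0.49 and Oxt at 1.33 ± 1.03; the median was 2.21 on VEGF array 2 and at most -0.54 on every other ischaemic array. Cerebellum markers were higher by 0.19 (adjusted p = 0.0261, adjusted p = 0.764 with an estimated correlation), and 1 of 8, Zic2, passed adjusted over the list alone, the only member of the 12 lists to do so. Without the pair, pituitary (median 1.85, adjusted p = 0.0765) and cerebellum markers (0.22, 0.195) did not pass.

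The remaining 29 lists did not pass in VEGF against MCAO, among them cytokines and chemokines (median -0.14, adjusted p = 0.115), endothelial markers (-0.03, 0.647), VEGF ligands, receptors and endothelial response genes (0.04, 0.361), neurotrophic and growth factors (0.08, 0.647) and neuron markers (0.09, 0.264). Medians and adjusted p of the rest were 0.10 and 0.321 for leukocyte adhesion, 0.14 and 0.361 for oxidative stress, 0.08 and 0.264 for unfolded protein response, -0.09 and 0.361 for p53 targets, -0.02 and 0.740 for hypoxia, -0.01 and 0.386 for proteases, 0.00 and 0.361 for reactive astrocyte, 0.03 and 0.275 for activated microglia and 0.25 and 0.361 for neutrophil genes. They were -0.10 and 0.670 for lymphocyte and -0.06 and 0.740 for complement genes, and -0.15 and 0.978 for immediate early, -0.14 and 0.275 for cell division, 0.10 and 0.213 for receptor and 0.04 and 0.361 for neurogenesis genes. The last were 0.14 and 0.101 for water channel, 0.21 and 0.0575 for glucocorticoid response, -0.05 and 0.978 for red blood cell, -0.50 and 0.275 for ependymal, 0.25 and 0.105 for thalamus, -0.25 and 0.749 for cortex and 0.10 and 0.231 for reference genes. Cytokine members with the smallest p were Il1rn at -1.51 ± 0.45 and Cxcl5 at -1.69 ± 0.88, endothelial ones Itm2a at 0.42 ± 0.36 and Abcb1a at -0.46 ± 0.42, and growth factors Egf at -0.49 ± 0.20 and Igf1 at 0.42 ± 0.26. Median, mean and test differed in sign for immediate early genes, oxidative stress, hypoxia, endothelial markers, proteases, growth factors, neurogenesis, and cortex and hippocampus markers. Without the pair of arrays 12 lists passed, 4 higher and 8 lower, the lower ones including cytokines and chemokines (-0.73, adjusted p = 4.55e-05), endothelial markers (-0.27, 0.00201) and immediate early genes (-0.46, 0.00222), and none held with an estimated correlation (lowest adjusted p = 0.463). Leaving out single arrays gave calls in both directions for some lists, and none of these calls held with an estimated correlation. Endothelial markers were lower without VEGF array 1 (-0.71, 7.76e-05) and higher without VEGF array 2 (0.34, 0.0263) or 3 (0.39, 0.0166), and immediate early genes lower without VEGF array 1 (-0.90, 7.76e-05) and higher without VEGF array 2 (0.24, 0.0483). Protease genes were lower without VEGF array 1 (-0.79, 0.000176) and higher without VEGF array 2 (0.30, 0.0102) or 3 (0.39, 0.00188). VEGF response genes were lower without VEGF array 1 (-0.43, 0.0387) and higher without VEGF array 3 (0.31, 0.0137). Neuron markers and receptors were lower without MCAO array 1 (-0.52, 0.0297 and -0.69, 0.0186) and higher without VEGF array 1 (0.75, 7.06e-06 and 0.87, 7.90e-06), MCAO array 2 (0.36, 0.0199 and 0.44, 0.00359) or MCAO array 3 (0.48, 0.00218 and 0.50, 0.00205). Cytokines and chemokines were lower without VEGF array 1 (-0.91, 3.17e-06) and without MCAO array 2 (-0.51, 0.00610). The count of lists was 7 without MCAO array 1. With the replicate block in the 6 ischaemic arrays, striatal neuron markers (adjusted p = 0.0297) and cholesterol synthesis (0.0265) also passed, against 0.105 and 0.0604 in the unblocked fit. Both had adjusted p = 0.737 with an estimated correlation.

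Each of the 12 lists lost its call with 1 array or more left out, interferon-stimulated genes as given above. The others did so as follows, with median and camera adjusted p in brackets, without VEGF array 1: heat shock (0.0316, 0.410), pericyte (-0.0842, 0.687), astrocyte (-0.0393, 0.540), homeostatic microglia (0.0474, 0.353), myelin genes (-0.43, 0.215), choroid plexus (-0.75, 0.302), meningeal (0.20, 0.410) and cerebellum (0.47, 0.111). Without VEGF array 2 these were cerebellum (0.0765, 0.218) and pituitary (0.0750, 0.828). Without VEGF array 3 these were oxidative phosphorylation (0.0910, 0.185) and choroid plexus (-0.52, 0.185). Without MCAO array 1 these were pericyte (0.37, 0.0974), astrocyte (0.31, 0.0715), interneuron (0.27, 0.283), myelin genes (-0.16, 0.484), oxidative phosphorylation (0.12, 0.0974), choroid plexus (-0.68, 0.144), meningeal (0.28, 0.246), cerebellum (0.15, 0.283) and pituitary (1.45, 0.1). Without MCAO array 2 these were heat shock (0.0909, 0.0918), myelin genes (-0.54, 0.0918) and pituitary (1.09, 0.174). Without MCAO array 3 these were heat shock (0.0970, 0.0858). Heat shock genes also missed the threshold with quantile normalization (0.13, 0.103) and the authors' value table (0.13, 0.106), and oxidative phosphorylation genes with quantile normalization (0.0546, 0.466) and the authors' value table (0.0497, 0.465). Cerebellum markers missed it with median centring (0.34, 0.0771), no filter on dim probes (0.10, 0.253) and named genes only (0.19, 0.0522). Pituitary markers missed it with median centring (1.48, 0.284), no filter on dim probes (0.87, 0.201), named genes only (1.33, 0.0637) and age as a covariate (0.87, 0.113). With array weights 8 of the 12 missed it: pericyte (0.14, 0.641), astrocyte (-0.0408, 0.753), homeostatic microglia (-0.0291, 0.75), interferon-stimulated (0.25, 0.312), interneuron (0.52, 0.0593), myelin (-0.40, 0.0966), meningeal (0.17, 0.385) and cerebellum genes (0.36, 0.0933). Choroid plexus markers were then higher (1.88, 0.00102). Cytokines and chemokines, short of it in the fit of all arrays, passed as lower with quantile normalization (-0.13, 0.0251), median centring (0.0163, 0.0160), normexp (-0.0416, 0.00129), the authors' value table (-0.13, 0.0249), named genes only (-0.14, 0.00912) and array weights (-0.49, 0.00102). No list held with an estimated correlation under any of these settings or with any array left out (lowest adjusted p = 0.325).

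The ischaemia signature was compared between VEGF and MCAO by a test that cannot pass 0.05 with 3 arrays against 3. This test and the SD given below take no account of any pairing by array number. The signature of 1307 genes higher and 427 lower in all ischaemic arrays scored 2.62, 1.54 and 1.74 on the MCAO arrays, 2.69, 1.28 and 1.37 on the VEGF arrays and -2.23, -1.78 and -1.90 on the sham arrays. VEGF minus MCAO was -0.19 log2 units, or -4.81% of the MCAO minus sham difference of 3.94, with a mean SD of 0.69 between arrays of a group, to which the high scores of arrays 1 contribute (exact two-sided permutation p = 0.6, where 0.1 is the smallest possible; fry p = 0.845). With arrays left out the signature genes were chosen anew, so those scores and differences are not on the scale of the ones above. VEGF minus MCAO was then 0.13 without MCAO array 1, 0.33 without VEGF array 2 and 0.17 without VEGF array 3. It was -0.65 without MCAO array 2, -0.47 without MCAO array 3 and -0.59 without VEGF array 1. Without both MCAO array 1 and VEGF array 1, a signature of 3894 genes higher and 5601 lower gave -0.17 (exact permutation p = 0.333, the smallest possible with 2 against 2). Its scores were 2.32 and 2.31 on the MCAO arrays, 2.15 and 2.14 on the VEGF arrays and 0.02, 0.30 and 0.21 on the sham arrays.

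The last pairwise comparison set the VEGF group against sham. The genes that rose most included Mmp3 (at least 342-fold), Msr1 (at least 135-fold), Clec4e (at least 118-fold), Slfn4 (at least 44.2-fold), Ccl2 (8.72 ± 0.63), Cxcl1 (7.81, limma adjusted p = 0.0110) and the transglutaminase gene Tgm1 (7.50 ± 0.42). Saa3 (9.85 ± 1.02) and Clec4d (8.40 ± 0.75), each well above background on 1 of 3 sham arrays, and the pentraxin gene Ptx3 (8.08 ± 0.77, 2 of 3) also rose. Chrna10 (-3.61 ± 0.58), Slc2a5 (-3.15 ± 0.46), Ankrd63 (-3.01 ± 0.49), Stpg1 (-2.78 ± 0.50), the thiamine transporter gene Slc19a3 (-2.57 ± 0.35), the nuclear receptor gene Nr4a2 (-2.57 ± 0.52) and Alox12e (-2.54 ± 0.44) fell, and Trim54 fell at least 4.40-fold. Retnla (-3.11 ± 0.43) and Igbp1b (-3.25 ± 0.68) fell too, each well above background on 1 of 3 VEGF arrays. In all, limma called 748 genes, 638 higher and 110 lower, and groups that did not overlap were found for 42.1% of genes, against 10% by chance.

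The median of all genes stood at -0.12 in VEGF against sham. Centring arrays on their median moved it to -0.03 and gave 1588 called genes. The count was 156 without sham array 1, 203 without sham array 2, 171 without sham array 3 and 3270 without MCAO array 1, of which 49.9% were higher, against 85.3% in the fit of all arrays. Fitting only the 2 groups, 61.6% were higher. Without both MCAO array 1 and VEGF array 1 it was 6175, and normexp gave 438.

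In VEGF against sham, 19 of 21 reactive astrocyte genes rose (21 adjusted over the list alone), with Lcn2 at 6.82 ± 0.34 and the copper oxidase gene Cp at 3.09 ± 0.24 (camera adjusted p = 1.36e-27, adjusted p = 0.0755 with an estimated correlation). Of 23 cytokines and chemokines 16 rose (21 adjusted over the list alone), with Ccl3 at 6.84 ± 0.47 (adjusted p = 1.14e-23, adjusted p = 0.107 with an estimated correlation). Of 18 activated microglia and macrophage genes 14 rose (16 adjusted over the list alone), with the lysozyme gene Lyz2 at 3.83 ± 0.29 (adjusted p = 3.28e-24, adjusted p = 0.107 with an estimated correlation). Of 19 interferon-stimulated genes 4 rose (17 adjusted over the list alone), Gbp2 (2.59 ± 0.23), Cxcl10 (5.50 ± 0.70), Ifitm3 (3.16 ± 0.52) and Bst2 (2.10 ± 0.44), with a median of 2.10 (adjusted p = 1.24e-13, adjusted p = 0.243 with an estimated correlation). Of 23 protease and matrix genes 9 rose (20 adjusted over the list alone), with Timp1 at 7.14 ± 0.46 (adjusted p = 7.75e-17, adjusted p = 0.243 with an estimated correlation). Of 15 neutrophil genes 7 rose (9 adjusted over the list alone), with Cxcr2 at least 22.4-fold (adjusted p = 5.37e-09, adjusted p = 0.261 with an estimated correlation). Of 14 complement genes 7 rose (12 adjusted over the list alone), with C5ar1 at 6.48 ± 0.51 (camera adjusted p = 7.12e-11, adjusted p = 0.107 with an estimated correlation). Of 21 p53 targets 7 rose (14 adjusted over the list alone), with Pmaip1 at 3.29 ± 0.36 (adjusted p = 4.96e-12, adjusted p = 0.243 with an estimated correlation).

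Neuronal lists were lower in VEGF against sham by camera at its preset correlation. Neuron markers had a median of -1.05 (adjusted p = 0.00554, adjusted p = 0.695 with an estimated correlation) and glutamate and GABA receptors of -1.22 (adjusted p = 0.00107, adjusted p = 0.632 with an estimated correlation). Striatal markers had a median of -1.18 (adjusted p = 0.00236, adjusted p = 0.632 with an estimated correlation). Cortex and hippocampus markers passed with adjusted p = 0.0331 (adjusted p = 0.632 with an estimated correlation). limma called 0 members of these 4 lists. At its unadjusted p under 0.05 were 1 of 16 neuron, 3 of 18 receptor and 5 of 14 striatal genes, against 7238 of all 30837 genes. Gabra2 stood at -1.46 ± 0.39 and Tubb3 at -1.49 ± 0.43, and 4 striatal markers were lower adjusted over the list alone. Without the pair of arrays the neuron median was -0.42 with 3 members lower, the receptor median -0.56 with 7 lower, and the striatal (median -0.87, adjusted p = 0.121) and cortex lists (-0.60, 0.157) did not pass. Among VEGF ligands, receptors and endothelial response genes Angpt2 (3.83 ± 0.61) and Adamts1 (4.24 ± 0.67) rose (adjusted p = 0.00462, adjusted p = 0.632 with an estimated correlation), while Vegfa stood at -0.06 ± 0.38, Flt1 at 1.22 ± 0.61, Kdr at 0.21 ± 0.18 and Nrp1 at -0.08 ± 0.28. Fgf2 (2.72 ± 0.41) and Hbegf (2.75 ± 0.50) rose among growth factors (adjusted p = 0.0330, adjusted p = 0.517 with an estimated correlation). Heat shock genes passed (median 0.79; 2.18e-07, adjusted p = 0.243 with an estimated correlation; 8 of 14 higher adjusted over the list alone), where Hspb1 rose by 4.80 ± 0.41. Oxidative stress and metal response passed too (1.03; 3.70e-07, adjusted p = 0.243 with an estimated correlation; 9 of 15 higher adjusted over the list alone), where Mt2 rose by 1.96 ± 0.28. Unfolded protein response (0.86; 4.57e-07, adjusted p = 0.202 with an estimated correlation), with Sdf2l1 at 1.34 ± 0.24, hypoxia response (0.43; 0.00240, adjusted p = 0.243 with an estimated correlation), with Adm at 2.69 ± 0.29, and glucocorticoid response (1.11; 2.62e-07, adjusted p = 0.107 with an estimated correlation), with Fkbp5 at 1.62 ± 0.24 and Sgk1 at 2.14 ± 0.34, also passed. So did leukocyte adhesion (1.34; 0.00155, adjusted p = 0.290 with an estimated correlation), red blood cell genes (1.08; 0.00192, adjusted p = 0.418 with an estimated correlation) and endothelial markers (1.11; 0.00544, adjusted p = 0.695 with an estimated correlation). Immediate early genes passed (0.68; 0.0330, adjusted p = 0.728 with an estimated correlation), with Atf3 at 6.22 ± 0.73, and not without the pair of arrays (-0.17; 0.494). Growth factors did not pass without the pair either (0.15, 0.106). In all, 23 lists passed, 19 higher and 4 lower, 0 with an estimated correlation and 15 with fry. Without the pair 20 passed, and 4 held with an estimated correlation: reactive astrocyte (adjusted p = 0.0345), activated microglia and macrophage (0.0210), protease (0.0210) and complement genes (0.0427). Reactive astrocyte and complement genes also held with median centring (both 0.0336) and without VEGF array 1 (0.00819 and 0.0110), activated microglia genes without VEGF array 1 (0.0451) and reactive astrocyte genes with array weights (0.0411). The other 18 lists did not pass, among them lymphocyte genes (median 0.40, adjusted p = 0.0540), choroid plexus (-2.02, 0.130), cell division (0.26, 0.124), myelin (0.60, 0.271), interneuron (-0.48, 0.195), oxidative phosphorylation (-0.04, 0.624), pericyte (0.45, 0.379), astrocyte (0.17, 0.275) and homeostatic microglia genes (0.49, 0.461), where P2ry12 fell by 2.31 ± 0.20. Also short of it were neurogenesis (-0.24, 0.528), water channels (-0.23, 0.624), cholesterol synthesis (-0.27, 0.169), ependymal (-0.37, 0.530), meningeal (0.52, 0.211) and reference genes (0.06, 0.271). Median, mean and test differed in sign for cerebellum (-0.02, adjusted p = 0.877), thalamus and midbrain (-0.02, 0.624) and pituitary and hypothalamus markers (-0.02, 0.810).

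Of the 23 lists past the threshold in VEGF against sham, 15 passed camera with each array left out in turn. The other 8 lost their call as follows, with median and adjusted p in brackets, without VEGF array 1: immediate early genes (-0.17, 0.658), VEGF response (0.11, 0.0649), endothelial (0.41, 0.176), neuron markers (-0.42, 0.194), glutamate and GABA receptors (-0.56, 0.0717), growth factors (0.15, 0.0649) and cortex and hippocampus markers (-0.60, 0.176). Without VEGF array 2 these were growth factors (0.51, 0.0546) and cortex and hippocampus markers (-0.98, 0.0832). Without sham array 1 these were immediate early genes (0.70, 0.0902). Without sham array 2 these were immediate early genes (0.44, 0.0911) and striatal markers (-0.71, 0.0855). Without sham array 3 these were growth factors (0.28, 0.0514) and cortex and hippocampus markers (-0.90, 0.0855). Immediate early genes missed the threshold with quantile normalization (0.68, 0.0587), median centring (0.76, 0.0696), normexp (0.57, 0.0545), the authors' value table (0.68, 0.0588) and named genes only (0.68, 0.0869). Growth factors missed it with quantile normalization (0.46, 0.0513), median centring (0.51, 0.0565), normexp (0.40, 0.0912), the authors' value table (0.46, 0.0506), named genes only (0.43, 0.0869) and the mean of a gene's probes (0.45, 0.0504). Cortex and hippocampus markers missed it with the mean of a gene's probes (-0.98, 0.0504). With array weights immediate early genes missed it (-0.24, 0.647).

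Both ischaemic groups were compared with the same sham arrays. Their log2 fold changes correlated at 0.914 across genes, where unchanged groups simulated against these sham arrays gave 0.501, and the covariance was 0.758 against 0.108 in simulation, a difference of 0.650. The simulation draws the groups independently, with no pairing of MCAO and VEGF arrays. Same-numbered arrays gave the means of the 2 groups a covariance of 0.0726, and 0.577 of the difference remained after taking it out. Signs matched in 85.0% of genes (66.6% in simulation). There were 619 genes called in both comparisons (0 in simulation), 552 higher and 67 lower, against 14.5 and 0.589 for independent lists, and 0 were called in opposite directions. The simulated groups were unchanged, so a count near 0 was fixed beforehand, and independent lists leave out the shared sham arrays. Neither count therefore measures how alike the 2 responses were. The controls were not divided, as 3 sham arrays do not give 2 to each part. The simulated correlation, covariance and sign share include the noise of shared sham arrays, as far as the simulation reproduces it. The counts for independent lists do not, so part of the excess over them may come from the shared controls. A slide or injection difference from sham would be common to both comparisons, is not in the simulation and cannot be told apart from ischaemia.

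Taking MCAO and VEGF together against sham, 1734 genes were called, 1307 higher and 427 lower. Besides genes named above, Slc22a8, an organic anion transporter gene (-3.11 ± 0.62), the serotonin receptor gene Htr5b (-2.91 ± 0.60) and the potassium channel partner gene Kcnip2 (-2.73 ± 0.64) were among the 10 largest falls. The count was 360 without sham array 1, 473 without sham array 2, 420 without sham array 3, 1047 without MCAO array 2, 1032 without MCAO array 3 and 4043 without MCAO array 1, of which 45.0% were higher against 75.4%. Without both MCAO array 1 and VEGF array 1 it was 9495, and age as a covariate gave 2783.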

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

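Leaving out the 14 discrepant probes, the recomputed signals, leaving out MCAO array 1 and VEGF array 1 together and the block in the 6 ischaemic arrays were chosen after results were seen. The slide could not be fitted as a block and was not run, since all sham arrays share a slide and all ischaemic arrays another. Signal over background limits the fold changes of genes near background in 1 group, which are given as lower bounds. Over 1025 comparisons of a list under an alternative with its main outcome, in MCAO against sham 50 lost a call by camera and 0 gained one. In VEGF against MCAO 71 lost a call, 91 gained one (21 of them against the main direction of the test) and 1 passed in the other direction, and in VEGF against sham 33 lost and 19 gained one. Of those that passed neither time, the test turned direction in 28, 112 and 26. The median itself took the other sign in 31, 141 and 50 of 1025, and in 161, 427 and 170 it did so or moved by over 1.5 times. Except where a construction shows it, the cause was not tested.

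Against 868, 2 and 748 genes called in MCAO against sham, VEGF against MCAO and VEGF against sham and 1734 with both ischaemic groups together, normexp gave 556 in the first, 0 in the second (280 at unadjusted p under 0.05 in limma) and 438 in the last. Median centring gave 1588 in VEGF against sham, and moved the median of all genes to -0.12 in MCAO against sham and 0.14 in VEGF against MCAO. Quantile normalization gave 4 in VEGF against MCAO, the filter on all 9 arrays 0 (580) and fitting only the 2 groups 1788 in MCAO against sham and 1 in VEGF against MCAO. Age as a covariate gave 1594 in MCAO against sham and 2783 together. Unadjusted p with a 2-fold difference gave 3534, 266, 3680 and 3791.

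Array weights gave 18457, 8391, 13189 and 16342 genes, a signature difference of 0.0732, and Nrp1 at 0.38 in MCAO against sham and -0.45 in VEGF against MCAO. camera with the weights passed 26, 16 and 24 lists, and with a variance trend, without the robust option that it lacks, 27, 14 and 23. List medians in VEGF against MCAO were -0.64 for immediate early, -0.46 for hypoxia, -0.34 for endothelial, -0.0408 for astrocyte, -0.0291 for homeostatic microglia, 0.25 for interferon-stimulated, -0.41 for neurogenesis, 1.88 for choroid plexus and -0.76 for cortex genes with the weights. The weight estimate did not converge, and MCAO array 2 had a weight of 57.6 where MCAO array 1 had 0.0782 and VEGF array 1 had 0.0958. The scan-day block takes out MCAO array 1, the only array of its day, and gave as many genes as leaving it out: 3270 in VEGF against sham and 4043 together. The signature difference was 0.15 with the block, which still counts the score of MCAO array 1, against 0.13 without the array. List medians in VEGF against MCAO were -0.52 for neuron markers and -0.69 for glutamate and GABA receptors.

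With the replicate number as a block in the 6 ischaemic arrays, VEGF against MCAO had 0 genes in limma (1164 at unadjusted p under 0.05), 0 with recomputed signals (1168), and 0 lists with an estimated correlation on either signal. The block in all 9 arrays gave 1229, 2, 946 and 2454 genes and 27, 12 and 24 lists, and it ended the call of neurotrophic and growth factors in MCAO against sham (adjusted p = 0.0572) and added lymphocyte genes in VEGF against sham (0.0461). Recomputed signals gave 853, 0 (865), 740 and 1725 genes, and leaving out the discrepant probes 853, 0 (846), 748 and 1726.

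Leaving out 1 array at a time gave 190 to 2583 genes in MCAO against sham, 1 to 3 in VEGF against MCAO, 156 to 3270 in VEGF against sham and 360 to 4043 together, and 7 to 18 lists in VEGF against MCAO. The signature difference, with its genes chosen anew each time, ran from -0.65 without MCAO array 2 to 0.33 without VEGF array 2. It was 0.13 without MCAO array 1 and 0.17 without VEGF array 3. List medians in VEGF against MCAO ran from -0.90 without VEGF array 1 to 0.29 without MCAO array 1 for immediate early genes, from -0.71 to 0.41 for endothelial markers and from -0.79 to 0.39 for proteases and matrix with the same arrays out. VEGF and endothelial response genes ran from -0.43 without VEGF array 1 to 0.31 without VEGF array 3. Neuron markers ran from -0.52 without MCAO array 1 to 0.75 without VEGF array 1, and glutamate and GABA receptors from -0.69 to 0.87 with the same arrays out.

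Without both MCAO array 1 and VEGF array 1, limma called 7028, 3, 6175 and 9495 genes, and 7054, 0 (2270), 6170 and 9522 with recomputed signals. List medians in VEGF against MCAO were then, with deposited and recomputed signals, -0.46 and -0.47 for immediate early genes, -0.12 and -0.13 for VEGF and endothelial response genes, -0.27 and -0.27 for endothelial markers and -0.13 and -0.13 for pericyte markers. They were -0.33 and -0.33 for proteases and matrix, -0.0425 and -0.0417 for astrocyte markers, and -0.0404 and -0.0432 for meningeal genes.

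Of the 28, 12 and 23 lists past camera's threshold, an estimated correlation left 0, 0 and 0 (lowest adjusted p 0.0807, 0.370 and 0.0755), directional fry gave 15, 0 and 15, and mixed fry gave 0 in VEGF against MCAO. Lists that passed under other settings included, in VEGF against MCAO, cholesterol synthesis with quantile normalization (adjusted p = 0.00158), normexp (3.34e-05), the filter on all 9 arrays (0.0224), the authors' table (0.00158) and named genes only (0.00325), glucocorticoid response with the mean of probes (0.0318), and p53 targets (0.00543), ependymal (0.0231) and thalamus genes (0.0448) with normexp. The scan-day block added neutrophil genes (0.0470), glucocorticoid response (0.0297), neuron markers (0.0297) and receptors (0.0186). Age as a covariate added neuron markers (0.00369), receptors (0.00369), striatal (0.0164) and ependymal genes (0.0279). In VEGF against sham they included lymphocyte genes with no filter (0.0137) or the mean of probes (0.0119), oxidative phosphorylation with quantile normalization (0.0392) and the authors' table (0.0393), interneuron (0.0461) and cholesterol genes (0.0260) with normexp, and choroid plexus markers with age (0.0481). None of these held with an estimated correlation (lowest adjusted p = 0.221). Component 1 held 68.7% of the variance with the 2000 most variable genes, against 57.0%.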

Other observations

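Choroid plexus markers differed between arrays of the same group. Their median relative to sham was 1.89 on MCAO array 1 and -0.28 on MCAO array 3 (lower still on MCAO array 2), -3.43, 1.18 and -3.15 on the VEGF arrays and 0.59, 0.49 and -1.12 on the sham arrays. Ependymal and cilia genes stood at 1.22, -0.11 and -0.57 on the MCAO arrays and -0.54, 0.48 and -1.02 on the VEGF arrays. Pituitary and hypothalamus markers stood at 2.21 on VEGF array 2 and between -1.13 and 0.45 on the other 8 arrays, and thalamus and midbrain markers at 1.02 on VEGF array 2 and -1.10 on VEGF array 1. Striatal markers ran from -0.72 to 1.00 among the sham arrays, and myelin genes from -0.82 to 0.90.

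The tests of Orm1 and Orm2 were chosen after the result was seen. As deposited, Orm1 had processed signals of 48800, 73900 and 48400 on the MCAO arrays, where the mean brightness of its spot was 83.8, 64.2 and 84 and local background 33, 38 and 38. With signals recomputed from the same spots, 0 of the 2 genes were called in VEGF against MCAO, which is consistent with the call coming from the departure of the deposited signals; how that departure arose is unknown. A lower level after VEGF injection cannot be told from the present data, since Orm2 still stood at -2.40 ± 0.29 with recomputed signals (limma adjusted p = 0.712).

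For MCAO array 1 and VEGF array 1, the spike-in and scan-day tests were chosen after the result was seen and the detrending test before. Weaker hybridisation or scanning of the whole array does not account for both, because the spike-in controls of VEGF array 1 lay -0.000815 log2 units from the mean of the other 4 ischaemic arrays (those 4 spanned 0.22), where MCAO array 1 lay at -0.36. Missing detrending does not account for MCAO array 1, which scored 129.7 on component 1 with its factor applied (the other 4 at most 15.7). A scan on another day does not account for VEGF array 1, scanned with the others (score 141). Both had low 75th percentile signals (923 and 848). Other causes, such as more injured tissue, were not tested. The labels give no infarct size.

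Arrays were also regrouped in every other way, as planned before the counts were seen. With 10 splits of 6 arrays, the real one counted among them, none can reach 0.05. In MCAO against sham, 1 of 10 splits had as many genes as the real one, which had 868 against at most 0, and 1 of 10 as many lists, 28 against at most 21. In VEGF against MCAO 1 of 10 had as many genes, 2 against at most 1, and 8 of 10 as many lists, 12 against at most 19. The 2 genes are Orm1 and Orm2, which were not called with recomputed signals, so this gene count rests on the discrepant signals. In VEGF against sham 1 of 10 had as many genes, 748 against at most 0, and 6 of 10 as many lists, 23 against at most 29. For both ischaemic groups together, fitted as 2 groups, 2 of 84 splits had as many genes as the real 2509. The other set MCAO array 1, MCAO array 2 and VEGF array 1 apart and had 2939.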
